A study of Homo sapiens with 12 samples.

How the data were processed

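RNA was measured in 22Rv1 cells, an established human prostate cancer cell line that expresses the androgen receptor and its splice variants. Per the labels' protocols, the cells were seeded as triplicates in a multi-well plate, and 1 set was kept in normoxia while the other was kept in hypoxia at 1% oxygen. Zotatifin, a small-molecule inhibitor of the RNA helicase eIF4A, was added at 10 nM 24 hours after seeding, for 24 hours. RNA was isolated with Trizol, and libraries were made from total RNA with a stranded SMARTer total RNA kit, per the labels' protocols. The 12 libraries fell into 4 groups of 3: normoxia with vehicle, hypoxia with vehicle, normoxia with zotatifin and hypoxia with zotatifin. The titles name the untreated cells vehicle, while their treatment tag reads none, and the solvent is not given in the sources used here. The titles call the libraries biological replicates, but nothing else says that they came from separate cultures or days. The p-values therefore set each change against the spread between these samples, which may be partly technical.

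The deposited values are estimated counts per feature, with 1 feature per line of the table and 12 columns, 1 per library. Of the values above 0, 33.2% were not whole to within 0.0005. Salmon, DESeq, DESeq2 and the human genome build hg38 are named in the submitters' processing notes, without versions, roles or order. The gene annotation is not given in the sources used here. The column totals differed between libraries, so the estimated counts as deposited were not scaled to a common total. A method that estimates counts divides reads shared by similar transcripts between them, so lines for near-identical copies are uncertain.

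The deposited table has no column or row names that identify its 60230 lines, so the files do not pair the lines with genes. Line numbers below count the data lines of the table from its first. No gene name was taken from the order of the lines. For this reason the 34 gene lists, the list tests and the gene symbols fixed in the design were not analysed here, and whether each line is a gene is not stated. The 4 lines printed by number are the 2 leading the rise and the 2 leading the fall with zotatifin in normoxia. Other extreme lines are described by their values only.

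Of the 60230 lines, 17388 had a value of 0 in every library and 42842 had a value above 0 in some library. The estimated counts were rounded to whole numbers. Lines were kept by edgeR's filterByExpr by group, with a minimum count of 10 and a minimum total of 15. This left 17993 lines, which are 42.0% of the lines above 0 and hold 99.8% of all counts. Library sizes were scaled by the trimmed mean of M values (TMM). The main test was edgeR's quasi-likelihood test (version 4.0.16, R 4.3.3), robust, with 1 mean per group over all 12 libraries and 8 residual degrees of freedom per line. It also borrows the spread across lines, with a median of 22.6 prior degrees of freedom, so small p-values do not rest on the libraries of that line alone. All tests were two-sided, with Benjamini-Hochberg adjustment over the 17993 lines and a threshold of 0.05. The common biological coefficient of variation was 6.11%. The 5 contrasts were hypoxia against normoxia in vehicle cells and in zotatifin cells, zotatifin against vehicle in normoxia and in hypoxia, and the interaction. The interaction is the effect of zotatifin in hypoxia minus that in normoxia, on the log2 scale. Standard errors were derived from each log2 fold change and its F statistic. Levels are given in CPM, the count divided by the TMM-scaled library size in M, as mean ± SD over 3 libraries. Correlations between libraries and principal components used log2 CPM with a prior count of 2.

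The lines described singly came from a rule fixed before the data were examined, except where stated. A line had to have an adjusted p under 0.05, a mean of at least 5 CPM in the higher group, and no overlap between the libraries of the compared groups. No such separation was asked for the interaction. The 10 lines with the largest rise and the 10 with the largest fall were then taken per contrast, leaving out the part of the rule that needs gene symbols. The text describes the first 2 of each and the range of the rest.

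Agreement between contrasts was measured as Pearson's r across lines, which are not independent replicates. The SD of true effects was estimated as the square root of the mean covariance between effects from separate libraries, over 9 ways of parting 3 against 3 libraries. Contrasts that share a group were set against 20 simulations without effects. Values per library were compared between oxygen conditions and between drug arms with exact two-sided permutation tests over 924 splits of the 12 libraries, adjusted over the 12 such tests. The interaction count was also set against 99 permutations of the residuals of a model with oxygen and drug effects alone, on log2 CPM with limma. For the gain of scarce lines in hypoxia, all lines were classed by the mean CPM of the normoxia libraries of the other drug arm, so that the filter and the libraries that measure the gain did not choose the class. To compare libraries at equal depth, each was thinned at random to 10394167 counts. Ratios of summed counts carry exact binomial intervals at 95%, which cover counting error only.

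The totals ranged from 10.4 to 16.5 M estimated counts (M, the SI prefix mega) per library. The methods were tested on simulated counts with the real means, dispersions and library sizes. With 50 of 17993 lines changed at each of 4 fold sizes in the hypoxia vehicle group, the vehicle-cell hypoxia contrast recovered 74% of the lines changed 1.5-fold, 76% of those changed 2-fold, 82% at 3-fold and 84% at 4-fold. It made 12 false calls. The interaction contrast on the same simulated counts recovered 54%, 64%, 72% and 78% at these sizes, with 7 false calls. These simulations changed few lines, while the real pairwise contrasts called 42.6% to 54.7% of them. The cut-off after adjustment depends on that share, so these rates and false calls need not hold for the real contrasts. A broad change that moves the scaling was not simulated. The noise-corrected SD recovered 0.495 of a true 0.500 on lines with a mean of at least 10 CPM, and 0.478 of 0.500 on all tested lines.

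The alternatives chosen before the data were examined were relative log expression and upper quartile scaling, no filter and a stricter filter, DESeq2 1.42.0, limma-voom (limma 3.58.1), a test against a fold of 1.5, the replicate number as a block, fits on the 2 compared groups alone, and leaving out each library in turn. The stricter filter asked for at least 1 CPM in 3 libraries and a mean count of at least 20. Added after seeing the data were equal depth, leaving out the 20 most abundant lines, and keeping only lines with a mean of at least 10 CPM. Figures were drawn with matplotlib 3.10.9.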

Results

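Expression in 22Rv1 prostate cancer cells was measured in a 2 by 2 design of oxygen and zotatifin, with 3 libraries in each of the 4 groups. The total estimated counts, in M (the SI prefix mega), were 16.1 ± 0.43 M in normoxia vehicle cells, 11.2 ± 0.91 M in hypoxia vehicle cells, 15.3 ± 1.05 M in normoxia zotatifin cells and 13.5 ± 2.70 M in hypoxia zotatifin cells (mean ± SD, n = 3 libraries each). The 6 hypoxia libraries were shallower than the 6 normoxia libraries, at 12.3 ± 2.19 against 15.7 ± 0.84 M (exact permutation p = 0.013, two-sided, adjusted p = 0.026 over 12 tests). The table lists 60230 unnamed features, 1 per line, and 17993 lines were tested. The files do not pair the lines with genes, so results are given as counts of lines, sizes of change and levels of single lines.

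Fewer counts did not mean fewer lines in hypoxia. Hypoxia vehicle cells had 29067 ± 1803 lines above 0 and hypoxia zotatifin cells 30204 ± 1706, against 24724 ± 692 in normoxia vehicle cells and 25200 ± 199 in normoxia zotatifin cells (SD, n = 3). With all libraries thinned to 10394167 counts, the hypoxia libraries held 28792 lines above 0 on average and the normoxia libraries 23721. All 6 hypoxia libraries lay above all 6 normoxia libraries (exact permutation p = 0.00216, two-sided, the smallest the 924 splits allow, adjusted p = 0.00519). Between the drug arms the number of lines at equal depth gave an exact permutation p = 0.755 (two-sided).

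**Figure D1:**
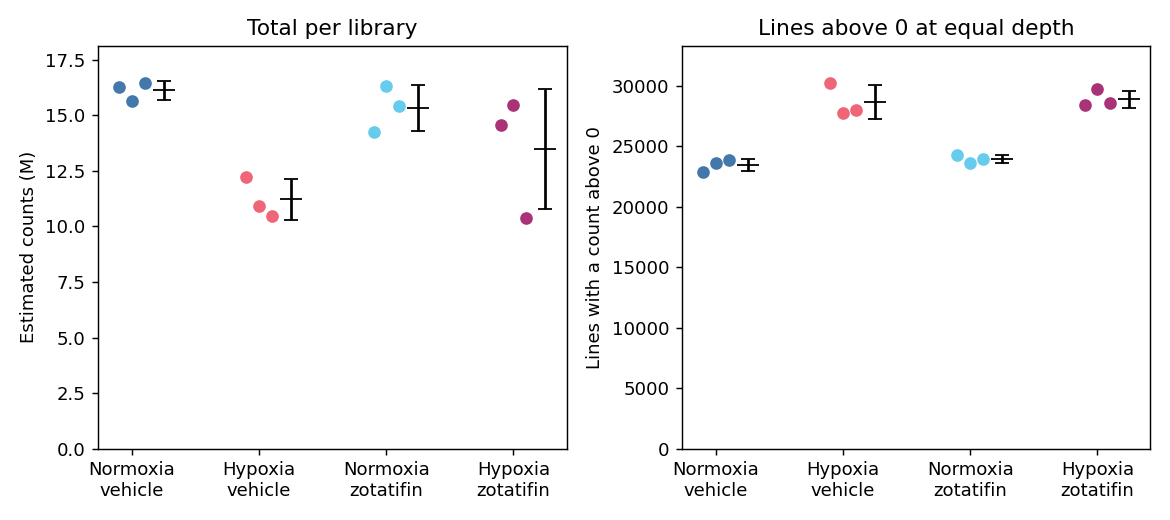
Total estimated counts in M (left) and number of lines above 0 after thinning every library to the smallest total (right), for each of the 12 libraries by group, with points for libraries and bars for the mean ± SD of 3. The hypoxia groups average 11.2 and 13.5 M counts against 16.1 and 15.3 M in normoxia, while all 6 hypoxia libraries lie above the normoxia libraries in lines at equal depth.

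Libraries of the same group were closer to each other than to any other group. Pearson's r of log2 CPM across the 17993 tested lines was 0.979 to 0.987 for the 12 pairs within groups and 0.931 to 0.968 for the 54 pairs between groups. No pair within a group agreed within sampling noise, since the chi-square statistic per degree of freedom was 3.02 to 15.1 in those pairs. Normoxia vehicle replicate 1 had 15.1 and 11.8 with the other 2 libraries of its group, against 5.10 between those, and normoxia zotatifin replicates 1 and 3 had 11.8 with each other. Normoxia vehicle replicate 1 also had the lowest TMM factor (0.932) and lay at -33.7 on the third principal component, with the others of its group at -7.48 and -4.65. Without it, the 5 contrasts called 7180, 8939, 10174, 8200 and 3497 lines, in the order hypoxia with vehicle, zotatifin in normoxia, zotatifin in hypoxia, hypoxia with zotatifin and interaction. The first principal component held 40.6% of the variance and the second 24.8%. The 4 groups formed 4 separate clusters on them.

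**Figure D2:**
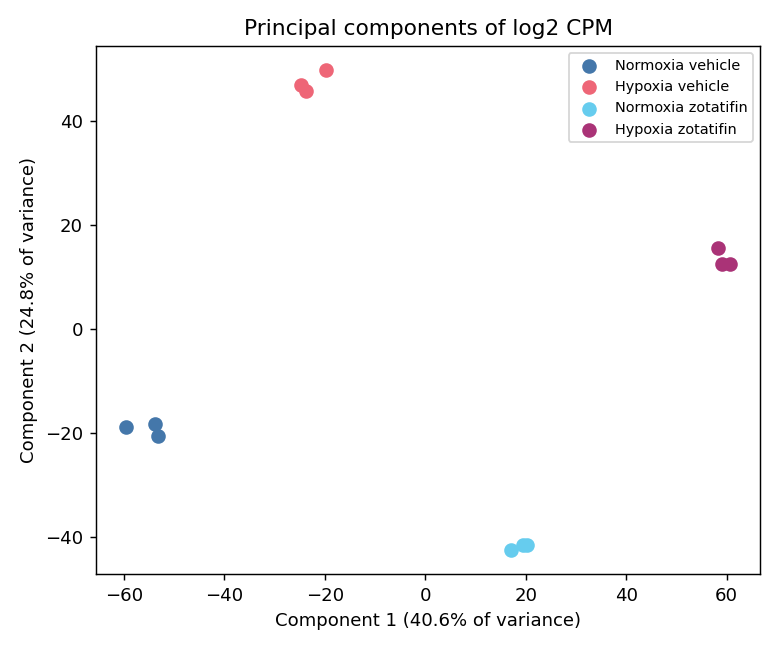
The first (40.6% of variance) and second (24.8% of variance) principal components of log2 CPM over the 17993 tested lines, with 1 point per library coloured by group. The 3 libraries of each group lie together, and the third component held 6.17%.

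The comparison of hypoxia with normoxia in vehicle cells asks what differed at 1% oxygen without the drug. Per the labels' protocols, 1 set of cells was kept in each oxygen condition. Any other difference between the sets therefore cannot be told apart from oxygen, in this and every other comparison of oxygen conditions. The single lines and rankings given for each comparison are those among called lines with at least 5 CPM in the higher group and, outside the interaction, no overlap between the groups. The line with the largest rise went from 0.022 ± 0.037 CPM in normoxia to 24.3 ± 0.78 CPM in hypoxia (SD, n = 3), or from 1 to 833 counts over the 3 libraries. That is a ratio of 1131 with an exact 95% counting interval from 203 to 44744 (log2 fold change 9.64, SE 0.37, edgeR adjusted p = 5.14e-19). Without normoxia vehicle replicate 2, which holds the 1 count, the fitted log2 fold change was 11.40, which is no bound. The next riser went from 0.66 ± 0.29 to 60.1 ± 3.27 CPM, a log2 fold change of 6.48 (SE 0.19). The line with the largest fall under these limits dropped from 48.7 ± 2.63 to 1.62 ± 0.43 CPM, a log2 fold change of -4.92 (SE 0.12, edgeR adjusted p = 5.8e-25). The next fell from 133 ± 13.0 to 21.6 ± 5.20 CPM (log2 fold change -2.62, SE 0.18). The 10 strongest rises spanned log2 fold changes of 9.64 to 3.54 and the 10 strongest falls -4.92 to -2.22, while called lines outside these limits reached -7.79.

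In total 7674 lines changed with hypoxia in vehicle cells (42.6% of those tested), 3007 higher and 4667 lower. Large changes went mostly upward, with 976 lines at least 2-fold higher against 277 at least 2-fold lower, and 306 against 42 at 4-fold. The 2-fold upward excess was largest among scarce lines but reached further. It was 136 lines higher against 43 lower from 4 to 16 CPM and 55 against 40 from 16 to 64 CPM. Over calls of any size the excess lay under 4 CPM. Under 1 CPM 341 lines rose and 31 fell, and from 1 to 2 CPM 278 rose and 63 fell. From 16 to 64 CPM 780 rose and 2231 fell, and at 64 CPM or more 617 rose and 1468 fell. The median log2 fold change moved from 0.44 under 1 CPM to -0.14 from 16 to 64 CPM and -0.10 at 64 CPM or more. Among lines of 64 CPM or more, 46 were at least 2-fold higher and 78 at least 2-fold lower. The split of the calls depended on scaling, with 39.2% higher under TMM, 43.3% under relative log expression factors and 60.3% under upper quartile scaling, where the median log2 fold change of all lines was 0.07 and not -0.05. It was 48.4% without normoxia zotatifin replicate 1, a library outside this contrast, and 48.8% without the 20 most abundant lines. In 49.9% of the tested lines the 3 hypoxia libraries did not overlap the 3 normoxia libraries, where chance gives 10%.

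**Figure D3:**
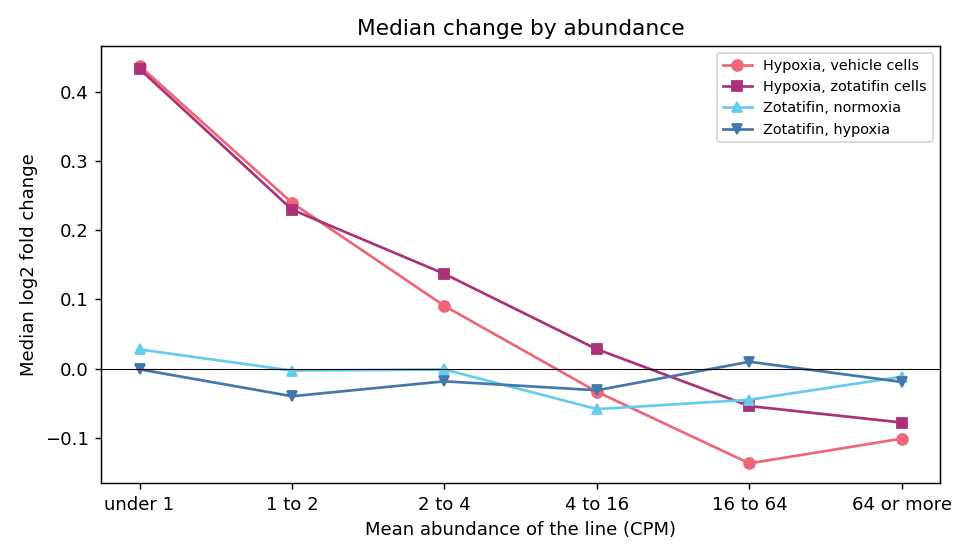
Median log2 fold change of the tested lines (vertical axis) in 6 classes of mean abundance in CPM (horizontal axis), with 1 curve for each of the 4 pairwise comparisons. Both hypoxia curves fall from 0.44 and 0.43 in lines under 1 CPM to -0.10 and -0.08 in lines of 64 CPM or more, while both zotatifin curves stay near 0.

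The comparison of zotatifin with vehicle in normoxia asks what inhibition of eIF4A changed in the RNA pool at normal oxygen. Line 365 rose from 2.11 ± 0.54 CPM with vehicle to 32.2 ± 1.74 CPM with zotatifin (SD, n = 3), a log2 fold change of 3.93 (SE 0.12, edgeR adjusted p = 1.22e-22). Line 56109 rose from 0.66 ± 1.14 to 14.0 ± 3.64 CPM, a log2 fold change of 4.42 (SE 0.73, edgeR adjusted p = 0.000785). All 30 vehicle counts of line 56109 lay in replicate 1 and the other 2 vehicle libraries listed 0, so its size rests on that library. Its ratio of summed counts was 21.8 with an exact 95% counting interval from 15.1 to 32.6. Without normoxia vehicle replicate 1 the fitted log2 fold change was 10.61, which depends on the prior count and is no bound, and limma-voom gave 6.79 with all libraries kept. Line 374 fell from 6.01 ± 0.83 to 0.57 ± 0.12 CPM (log2 fold change -3.38, SE 0.29, edgeR adjusted p = 1.78e-11). Line 2144 fell from 23.9 ± 3.24 to 2.30 ± 0.10 CPM (log2 fold change -3.37, SE 0.14, edgeR adjusted p = 3.28e-19). The 10 strongest rises spanned 4.42 to 2.80 and the 10 strongest falls -3.38 to -2.38.

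Zotatifin in normoxia changed 9538 lines (53.01% of those tested), 4518 higher and 5020 lower. At least 2-fold, 953 were higher and 893 lower, and at least 4-fold, 177 were higher and 78 lower. The split was near even: 47.4% were higher under TMM, 50.8% under upper quartile scaling, and 47.1% to 54.3% with 1 library left out. The median log2 fold change of all lines was -0.03, and the median size among called lines was 0.55. The 3 zotatifin libraries did not overlap the 3 vehicle libraries in 58.0% of the tested lines, where chance gives 10%.

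The same drug comparison in hypoxia asks whether the response held at 1% oxygen. Line 365 rose from 14.0 ± 0.39 to 212 ± 15.8 CPM (SD, n = 3), a log2 fold change of 3.91 (SE 0.08, edgeR adjusted p = 1.74e-27). This line also rose with hypoxia in both drug arms, by log2 fold changes of 2.74 with vehicle and 2.72 with zotatifin, so that its mean was lowest in normoxia vehicle cells and highest in hypoxia zotatifin cells. Its interaction was -0.02 (SE 0.14, edgeR adjusted p = 0.951). Line 56109 rose from 0.10 ± 0.18 to 18.7 ± 2.12 CPM (log2 fold change 7.21, SE 1.02, edgeR adjusted p = 0.000284). Its 4 vehicle counts in hypoxia all lay in replicate 1, which gives a ratio of 159 with an exact 95% counting interval from 61.7 to 584. Without hypoxia vehicle replicate 1 the fitted log2 fold change was 11.03, again no bound. Line 2144 fell from 29.3 ± 1.45 to 1.11 ± 0.25 CPM (log2 fold change -4.74, SE 0.16, edgeR adjusted p = 2.17e-21). The next faller dropped from 18.4 ± 0.28 to 1.68 ± 0.24 CPM (log2 fold change -3.45, SE 0.18). Line 374 went from 5.60 ± 0.80 to 0.70 ± 0.34 CPM (log2 fold change -2.98, SE 0.30, edgeR adjusted p = 2.96e-10). The 10 strongest rises spanned 7.21 to 3.09 and the 10 strongest falls -4.74 to -2.63.

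Zotatifin in hypoxia changed 9850 lines (54.7% of those tested), 4987 higher and 4863 lower. At least 2-fold, 1230 were higher and 1024 lower, and at least 4-fold, 193 were higher and 127 lower. Of the calls, 50.6% were higher under TMM, 47.3% under upper quartile scaling and 45.1% without the 20 most abundant lines. The median log2 fold change of all lines was -0.01. No overlap between the 3 libraries of each arm was seen in 61.4% of the lines, where chance gives 10%.

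Hypoxia against normoxia in zotatifin-treated cells changed 7686 lines (42.7%), 3650 higher and 4036 lower. Among lines within the limits, the second-ranked riser of vehicle cells led here, from 0.26 ± 0.29 to 33.5 ± 0.37 CPM (SD, n = 3, log2 fold change 6.94, SE 0.24, edgeR adjusted p = 8.23e-16). Its 12 normoxia counts were uneven between libraries, and the log2 fold change was 8.26 without normoxia zotatifin replicate 3 and 6.33 without replicate 2. Another line rose from 0.55 ± 0.14 to 23.1 ± 1.29 CPM (log2 fold change 5.37, SE 0.19). The line that fell most in vehicle cells fell most here too, from 101 ± 1.76 to 4.90 ± 0.26 CPM (log2 fold change -4.37, SE 0.09, edgeR adjusted p = 2.66e-27). The next faller dropped from 33.3 ± 2.85 to 4.25 ± 1.04 CPM (log2 fold change -2.94, SE 0.14). The line with the largest rise in vehicle cells was listed at 0 in all 3 normoxia zotatifin libraries and at 4.92 ± 1.47 CPM in hypoxia zotatifin cells. It had the largest called rise here too (fitted log2 fold change 9.13, SE 0.57, edgeR adjusted p = 9.69e-14), which is no bound. Only the limit of 5 CPM kept it out of the ranking. At least 2-fold, 937 lines were higher and 306 lower. The median log2 fold change again fell with abundance, from 0.43 under 1 CPM to -0.08 at 64 CPM or more. The calls were 47.5% higher under TMM and 56.9% under upper quartile scaling. No overlap between groups was seen in 53.1% of the lines, where chance gives 10%.

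**Figure D4:**
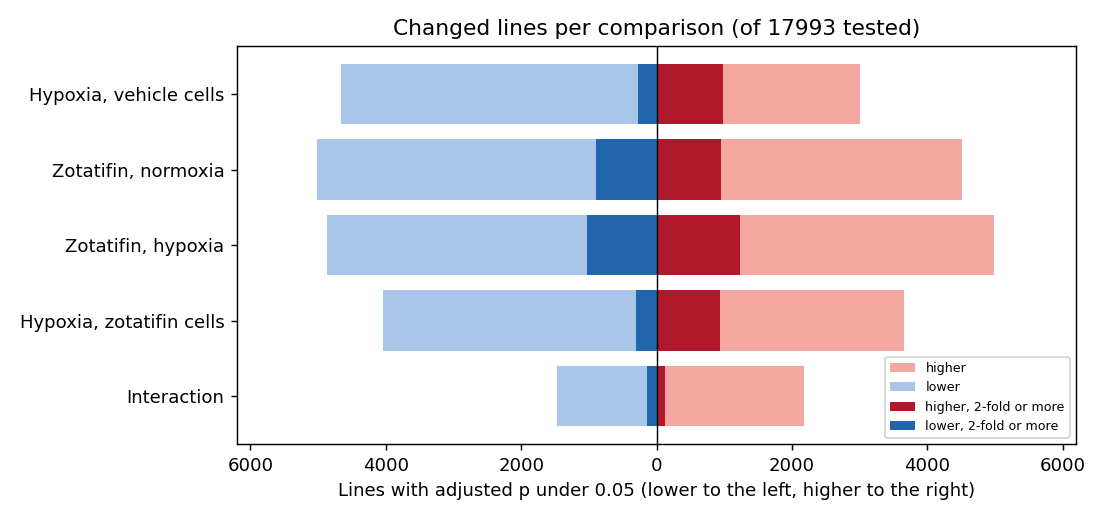
Number of lines with an adjusted p under 0.05 in each of the 5 contrasts, with bars to the right for higher and to the left for lower lines and darker parts for changes of at least 2-fold. Zotatifin changed 9538 and 9850 lines, hypoxia 7674 and 7686, and the interaction 3655, under TMM scaling. Upper quartile scaling turns the larger side in both hypoxia contrasts, in zotatifin against vehicle in both oxygen conditions, and in the interaction.

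The effect of zotatifin was similar in normoxia and hypoxia across lines, and these contrasts share no libraries. Pearson's r was 0.674 over the 17993 tested lines and 0.864 over the 10320 lines with a mean of at least 10 CPM, where the slope was 0.972 and 81.8% of lines had the same sign. With counting and replicate noise removed, r was 0.877 and 0.889 on these sets. Lines called higher in both numbered 3480, where independent lists of these lengths give 1252, and lines lower in both numbered 3609, where independent lists give 1357. Calls in opposite directions numbered 119 and 153, where independent lists give 1221 and 1391. Without noise, the SD of the log2 effects over lines of at least 10 CPM was 0.534 in normoxia (0.527 to 0.544 over 9 splits) and 0.608 in hypoxia (0.605 to 0.612).

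The effects of hypoxia in the 2 drug arms, which again share no libraries, were compared in the same way. Pearson's r was 0.623 over all tested lines and 0.712 over lines of at least 10 CPM, where the slope was 0.708 and 69.3% of lines had the same sign. With noise removed, and effects again taken from log2 CPM, r was 0.821 and 0.759. The difference of the hypoxia effects equals that of the zotatifin effects in every line, so r also depends on the size of the effects, and the difference between the correlations for hypoxia and for zotatifin was not tested. Lines higher in both arms numbered 1682, where independent lists give 610, and lines lower in both numbered 2478, where independent lists give 1047. The noise-corrected SD over lines of at least 10 CPM was 0.401 with vehicle (0.391 to 0.406) and 0.402 with zotatifin (0.399 to 0.407). At 16 CPM or more, 60 lines rose and 80 fell at least 2-fold in both arms.

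**Figure D5:**
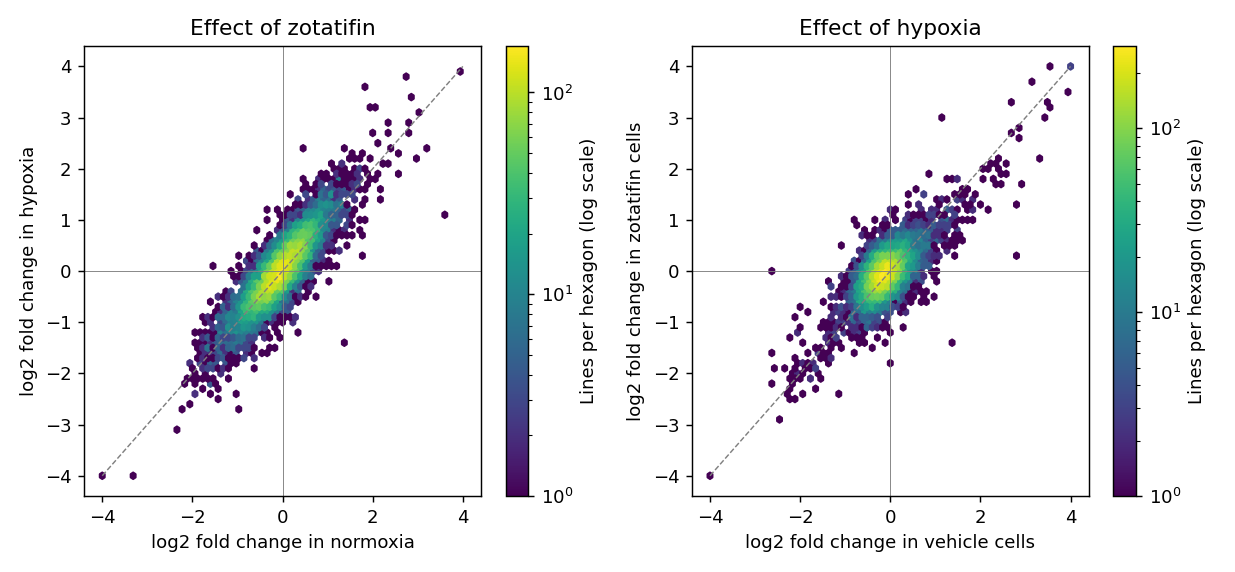
Log2 fold changes of the 10320 lines with a mean of at least 10 CPM, for zotatifin in normoxia against hypoxia (left) and for hypoxia in vehicle against zotatifin cells (right), with values beyond the axis ends drawn at the ends, colour for lines per hexagon on a log scale and a dashed line of equality. Pearson's r is 0.864 on the left and 0.712 on the right.

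The interaction asks which lines responded differently to zotatifin in hypoxia and normoxia. The leading line stood at 1.79 ± 0.73 CPM in normoxia vehicle, 1.81 ± 0.81 in hypoxia vehicle, 1.13 ± 0.19 in normoxia zotatifin and 13.4 ± 1.44 CPM in hypoxia zotatifin cells (SD, n = 3 each). Its interaction was 3.57 on the log2 scale (SE 0.40, edgeR adjusted p = 2.51e-07). The next also rose with the drug in hypoxia, from 4.22 ± 1.22 to 24.1 ± 1.52 CPM, and stood at 2.36 ± 0.41 and 1.89 ± 0.13 CPM in normoxia (interaction 2.85, SE 0.27). On the negative side a line went from 5.65 ± 0.55 to 0.87 ± 0.16 CPM with zotatifin in hypoxia and stood at 2.83 ± 0.18 and 2.61 ± 0.42 CPM in normoxia (interaction -2.60, SE 0.35). Another rose with the drug from 2.01 ± 0.62 to 24.5 ± 1.55 CPM in normoxia and from 13.9 ± 0.84 to 30.5 ± 0.40 CPM in hypoxia (interaction -2.47, SE 0.18, edgeR adjusted p = 3.38e-11). Line 2144 fell further in hypoxia than in normoxia (interaction -1.37, edgeR adjusted p = 0.00019).

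In all, 3655 lines passed the interaction test (20.3%), 2184 positive and 1471 negative. Most differences were small, with 120 lines at least 2-fold positive and 134 at least 2-fold negative. Of the 3655 lines, 1719 were called for zotatifin in both oxygen conditions with the same sign and 272 with opposite signs. The balance of signs depended on scaling and on the libraries kept. Positive calls made up 59.8% under TMM, 52.6% under relative log expression factors and 43.3% under upper quartile scaling. They made up 45.0% without normoxia zotatifin replicate 1 and 38.8% without the 20 most abundant lines. Leaving out normoxia zotatifin replicate 1 also moved the share of higher calls for hypoxia in vehicle cells, from 39.2% to 48.4%. That library takes no part in the vehicle-cell contrast, so its removal acts there only through the refitted scaling, filter and spread.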

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

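The tests of depth, scaling and background and the permutation of residuals below were chosen after the patterns were seen. Leaving out each library and counting other splits were planned, and the bound set on the first was chosen after. No group has 4 or more libraries, so no single library was tested for standing apart from its group; the report gives the values in which normoxia vehicle replicate 1 differed from the other libraries of its group.

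The share of counts in lines too scarce to be tested was 0.243% ± 0.033 in the 6 hypoxia libraries and 0.126% ± 0.005 in the 6 normoxia libraries (SD, exact permutation p = 0.00216, two-sided, the smallest that 924 splits allow). This was seen outside the tested lines, and scarce tested lines went the same way: of the 1963 lines under 1 CPM, 70.5% had a higher mean in hypoxia with vehicle and 68.6% with zotatifin. Lower depth in hypoxia was argued against for the number of lines above 0. The shallower hypoxia libraries led before thinning, with 28012 or more against 25407 or fewer. At equal depth the hypoxia library with the fewest lines above 0 still had 3484 more than the normoxia library with the most. The untested lines then held 22427 to 30895 counts in hypoxia and 12486 to 13699 in normoxia. Neither value measures the fold changes of scarce tested lines. A single scaling factor per library was also argued against, since it would move all lines alike and the median log2 change of lines under 1 CPM exceeded that of lines of 64 CPM or more by at least 0.511 in both drug arms. A background added to every line at about the same rate was not settled by the gains. Among all lines, tested or not, classed by the normoxia level of the other drug arm, the median gain in hypoxia with vehicle was 0.133 CPM in lines of 0.5 to 1 CPM (95% bootstrap interval over lines 0.111 to 0.152), 0.174 (0.133 to 0.217) at 1 to 2 CPM and 0.176 (0.119 to 0.237) at 2 to 4 CPM, with overlapping intervals, as a like rate would give. With zotatifin it was 0.120 (0.104 to 0.140), 0.160 (0.131 to 0.191) and 0.222 (0.169 to 0.287), a ratio of 1.84 between the last and the first, whose intervals do not overlap, so the arms do not agree. A difference in scale between the conditions would change each gain in proportion to the level. Lines of 64 CPM or more had median log2 changes of -0.10 with vehicle and -0.08 with zotatifin. Gains were taken under TMM scaling only, so the overlap or its absence may reflect scaling. With vehicle, lines of 0.1 to 0.25 CPM gained 0.0639 (0.0577 to 0.0707) and lines of 0.25 to 0.5 CPM 0.106 (0.0961 to 0.118). With zotatifin these gains were 0.0644 (0.0578 to 0.0701) and 0.0794 (0.0699 to 0.0918). In both arms these intervals lie below those at 2 to 4 CPM, narrowly so with vehicle at 0.25 to 0.5 CPM. That goes against a like rate over these classes under TMM scaling. Lines of 0.03 to 0.1 CPM gained 0.0404 and 0.0372, but they lie too near 0 to decide. A background that differs between lines (with their length, for example), a library batch that follows oxygen, and wider transcription in hypoxia all stay open and were not tested, since the lines carry no names or lengths.

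The effect of zotatifin differed between hypoxia and normoxia in 3655 lines by the interaction test. In 100 splits of the 12 libraries into 4 groups of 3, the real one was the 1 with as many calls and the highest of the others gave 2612, but the other splits carry the oxygen and drug effects in their spread, so they decide nothing here. With those main effects kept in place and the remaining deviations permuted over the libraries, 3 of 100 orders, the real one included, gave at least the 3517 calls that limma's trend method makes on log2 CPM, a share under 0.05, with 4851 calls in the highest other order. Of the 99 other orders, 92 gave 0 calls. The permuted deviations still hold any interaction, which widens the spread in those orders, so their low counts add little weight. Background confined to scarce lines was argued against as the whole cause, since 95.9% of the calls lay in lines of 4 CPM or more, which it does not reach. Most tested lines lie at that level, and scarce lines were seldom called, with 13 positive and 21 negative of 1963 under 1 CPM. The share therefore says little about the calls in scarce lines. Unequal depth and a single deviating library were argued against likewise, since 3306 calls were made at equal depth and 2932 in the fewest case with 1 library left out. A difference in the response to zotatifin between the oxygen conditions may account for the pattern and stays a hypothesis, and a batch following 1 of the 4 groups was not tested.

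Among the lines described singly, 7 had effects that differed by the interaction test. The described line that fell most with hypoxia had an interaction of 0.55 (edgeR adjusted p = 0.0496), a call that ended in 19 of 23 alternatives, among them the loss of any 1 library other than hypoxia vehicle replicate 2 (0.74) and normoxia vehicle replicate 3 (0.58), with values from 0.37 without hypoxia vehicle replicate 1 to 0.59 without hypoxia zotatifin replicate 2. Line 2144 had -1.37, and the second-ranked faller with zotatifin in hypoxia had -0.96 (edgeR adjusted p = 0.00982). The 4 lines that lead the interaction had 3.57, 2.85, -2.60 and -2.47.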

How the results depend on the processing

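The counts of changed lines stayed within 1.5 times their values under every scaling, filter, test and library left out, except in the test against a fold of 1.5. That test, by construction stricter, called 852 lines for hypoxia with vehicle, 2234 for zotatifin in normoxia, 2945 for zotatifin in hypoxia, 856 for hypoxia with zotatifin and 65 for the interaction. With 1 library left out, these counts ranged over 6637 to 7748, 8750 to 9540, 9140 to 10174, 6564 to 8200 and 2932 to 3586. The correlation of zotatifin effects was 0.806 under the stricter filter and 0.864 over lines of at least 10 CPM, and 0.606 to 0.637 with 1 library left out. That of hypoxia effects was 0.680, 0.712 and 0.552 to 0.611. The filters test fewer scarce lines, by construction. The fits with 1 library left out had both fewer libraries and 18273 to 18699 tested lines, and the cause of their lower correlations was not tested. DESeq2 called 7388, 9010, 9573, 7422 and 3630 lines in the same order. The shares of higher calls, by contrast, depended on scaling, and the cause was not tested. Which lines were called moved more than the totals. Under upper quartile scaling, 5891 of the 7260 lines called for hypoxia with vehicle were among the 7674 of the main fit. For the 15 lines taken by the rule, all 468 values in their own contrasts kept direction and significance, with an adjusted p of at most 0.0336, although sizes moved where the lower group had few counts: limma-voom gave 6.79 and not 4.42 for line 56109 in normoxia, and equal depth gave 11.001 and not 9.643 for the largest rise with hypoxia. The rule took these lines from the same libraries for large, called changes, so that they stayed called was largely set by the choice. For hypoxia with zotatifin, the calls of the largest vehicle-cell riser and of the most abundant line were not followed through the alternatives. Another 11 printed calls of single lines kept direction in all 254 values and significance in 229. Of the 25 that did not, 19 belong to the interaction of 0.55 (0.37 to 0.74 over its alternatives), 5 to the test against a fold of 1.5, and 1 to limma-voom for the interaction of -0.96 (-0.97, adjusted p = 0.0609). The numbers do not pair the libraries: the 18 same-numbered pairs had residual correlations of -0.077 to 0.036, and 2 of 12 libraries correlated best with their own number. The replicate block gave 7731, 9553, 9868, 7720 and 3797 lines and correlations of 0.676 and 0.625. Not run, for want of gene names, were the gene lists and their alternatives (fry, and camera with an estimated correlation) and leaving out mitochondrial, structural RNA and histone genes. Depth limits the scarce lines, since 16813 lines passed the filter at equal depth and 17993 at full depth. In all, 42237 lines were not tested, 17388 of them at 0 in every library, and how many of these are not expressed was not tested.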

Other observations

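The correlation test over lines of at least 10 CPM was planned before its result was seen, as were the counts of other splits; the comparison with simulations, and the abundant lines described next, were chosen after values were seen.

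The most abundant line by its mean over all 12 libraries took 3.48% ± 0.42 of the counts in normoxia vehicle cells, 2.21% ± 0.12 in hypoxia vehicle cells, 3.31% ± 0.42 in normoxia zotatifin cells and 2.57% ± 0.18 in hypoxia zotatifin cells (SD, n = 3). It was lower in hypoxia by the edgeR test, with vehicle (log2 fold change -0.74, adjusted p = 0.0025) and with zotatifin (-0.40, adjusted p = 0.0421). Its interaction was 0.33 (edgeR adjusted p = 0.296). The second most abundant line took 1.12% ± 0.06, 1.62% ± 0.06, 2.17% ± 0.02 and 2.82% ± 0.07 of the counts in the same order of groups, so that it led in hypoxia zotatifin cells. It rose with zotatifin in normoxia (log2 fold change 0.92, edgeR adjusted p = 3.11e-19) and in hypoxia (0.80, edgeR adjusted p = 8.58e-18), with an interaction of -0.13 (edgeR adjusted p = 0.0999). It also rose with hypoxia, by 0.46 with vehicle and 0.33 with zotatifin. The 10 most abundant lines of each library, chosen library by library, together took 12.2% to 16.5% of its counts.

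The average hypoxia effect and the average zotatifin effect, a balanced pair over all 4 groups, had Pearson's r = 0.182 across the tested lines, and 20 simulations without effects gave -0.144 to 0.038. The observed covariance exceeded the simulated one by 0.0798. In a balanced pair with lines simulated independently, errors nearly cancel, so simulated values near 0 were set by the design. Deviations shared by many lines of a library were not simulated, so these simulations decide nothing about them. With effects taken from log2 CPM in place of edgeR's fit, r was 0.191 over all tested lines. Over the 10320 lines with a mean of at least 10 CPM it was 0.256 (0.244 to 0.265 with each library left out in turn), which argues against background in scarce lines. Of these lines, 54 were at least 2-fold lower and 16 at least 2-fold higher in both averages, while 8 went in opposite directions. That 1% oxygen and zotatifin may act in part on the same RNAs is a hypothesis found and tested on the same data, and a common change such as slower growth was not tested.

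With vehicle controls shared, the overlaps are harder to read. Hypoxia in vehicle cells and zotatifin in normoxia, which share the normoxia vehicle libraries, had r = 0.338, where simulations without effects averaged 0.479, and the observed covariance of 0.180 exceeded the simulated 0.0607 by 0.119. Both contrasts called 1127 lines higher and 2234 lower, where independent lists give 755 and 1302, and 564 and 1061 in opposite directions, where independent lists give 839 and 1172. Hypoxia in vehicle cells and zotatifin in hypoxia, which share the hypoxia vehicle libraries with opposite signs, had r = -0.086, where simulations averaged -0.528, and the covariance exceeded the simulated one by 0.0210. These contrasts called 733 lines higher in both and 1706 lower in both, where independent lists give 833 and 1261, while 936 rose with hypoxia and fell with zotatifin and 1688 did the reverse, where independent lists give 813 and 1294. Splitting the 3 controls leaves 1 library in a part, so some of any excess may come from them, while in the balanced pair, with its r of 0.182, no group is used as the control of both effects alone.

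Each of the 4 pairwise counts was set against the other splits of its 6 libraries in a fit of those libraries alone. There are 10 splits, too few for a share under 0.05. The real splits, each 1 of 10, gave 6485 lines for hypoxia with vehicle, 9085 for zotatifin in normoxia, 9991 for zotatifin in hypoxia and 8065 for hypoxia with zotatifin, and the highest of the others gave 0 in each by edgeR's adjusted p and 93 to 280 lines at an unadjusted p under 0.05. The other splits mix treated and untreated libraries, so the effect itself widens their spread, and their low counts decide nothing.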
